A study of Drosophila melanogaster with 2 samples.

How the data were processed

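The series held 1 group of 2 biological replicates, per the labels, of chromatin from 2 to 12 h embryos of a line with a GFP fusion of E(spl)mδ-HLH, sheared by sonication to fragments of 200 to 800 bp. A free-text label describes the samples as input control, while the assay label, the antibody label and a separately listed control point to immunoprecipitated chromatin. The samples were treated as immunoprecipitated, since each has peaks called against a control. The label for embryo age is garbled in 1 field, and the age was taken from the source label.

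The authors deposited 4 peak lists on assembly dm6 in narrowPeak layout: 1 per replicate, 1 called on both replicates pooled, and 1 thresholded on the irreproducible discovery rate. Per the deposited file listing, every list was called against the same control alignment. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, an enrichment statistic per list, and it was used only to rank and describe peaks within a list. The q value column, deposited as −log10 of the q value, reached its ceiling in 2029 of the 2750 thresholded peaks, so it ranks strong peaks poorly. The summit offset was deposited as another column, a distance in bp from the peak start. The lists of 30000 peaks include background, as their deposited type says, and end at a fixed length. Read depth is unknown, so no statement rests on it. Median peak widths were 250 bp in the thresholded list, 244 bp in replicate 1 and 256 bp in replicate 2.

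Coordinates are 1-based on dm6. Genes, transcripts and start sites came from the Ensembl annotation of BDGP6, and sequence from the NCBI Release 6 genome, the same assembly as dm6. As a check, 16193 of 16213 annotated start codons read ATG in that genome, and 0 peaks ended beyond a chromosome arm. Peaks on arms 2L, 2R, 3L, 3R, 4 and X were used. Summits were classed in order of priority as within 500 bp of a protein-coding TSS, 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Start sites of other kinds of genes did not count as TSSs in these classes. A protein-coding gene was called bound if a thresholded summit lay within 2 kb of any of its TSSs.

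Gene lists, motifs, tests, the rule for named genes and all alternatives except 2 were fixed before the data were examined. The 17 lists were the E(spl) complex, the Bearded complex, proneural and sense organ precursor, Notch pathway, neuroblast, segmentation, Hox, dorsoventral patterning, mesoderm and muscle, trachea and midline, glial, endoderm and hemocyte, germline, neuron differentiation, cell cycle, cytosolic ribosomal protein and odorant receptor genes. All listed names matched the annotation, 5 of them under a newer symbol, except 2 of the 6 Bearded complex genes. Named genes were E(spl)mdelta-HLH, up to 4 bound members per list with the highest signal within 2 kb of a TSS, and the protein-coding gene with the nearest TSS to each of the 15 strongest peaks. 1 gene that the rule selects is not reported here. Other members are named as examples of bound or unbound genes and were chosen after their values were seen.

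Lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, motifs with exact McNemar tests of windows reaching 50 bp to either side of the summit against windows centred 500 bp to the left, and the strongest 550 against the weakest 550 peaks with Fisher's exact tests. Each family was adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Genes in a list can share a peak, so the exact tests take as independent what is partly linked. The same lists were run against 10000 random gene sets matched on TSS number and spacing. Those sets do not keep neighbouring genes together, so they do not correct for shared peaks either. Locations were compared with 100 circular shifts of the summits and loci with 10000 random windows on the same arm, with seed 1. Shares carry exact binomial 95% intervals, and a count of 0 is given the limit of 3 counts. Peaks matched between replicates if their summits were within 100 bp and overlapped if they shared at least 1 bp. The IDR was fitted as a copula mixture of a reproducible and an irreproducible component on signal ranks, calling no pair where the mixture fitted no better than independence. Analyses used python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9.

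The statistics were tested on simulated data. For the IDR count, 11100 simulated pairs with 45.8% reproducible gave a fitted share of 46.5%, and 5.68% of the 3382 pairs called were irreproducible. In 10 draws of independent pairs, 0 had a call. A first version of the fit called every independent pair, and the comparison with independence was added for that reason. For the gene lists over 13945 genes, 3 of 100 families of random lists gave a call, and all 100 planted lists with 12 of 20 genes bound were called. Each planted list had the same number of bound genes, so its call was fixed in advance. The planted lists do not give the power for smaller lists or lower shares. For the motifs over 2750 windows, 0 motifs differed between left and right flanks, and all 137 planted CACGTG sites were found. The planted sites check only the search for the sequence. The flanks had a like GC content (42.0% and 41.6%), so they do not test the motif comparison under a GC difference.

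Alternatives covered the overlap and matching distance, the number of top peaks, the ranking column, the IDR threshold, the TSS distance, the rule for bound genes, matched gene sets, the strongest 1375 peaks, each replicate's top 2750 peaks alone, the motif window, and other control sequences. The 2 added after seeing the data were motif control windows matched on GC content and location class, and gene lists without the peaks of the E(spl) complex. Lists of translation factor, proteasome core and mitochondrial ribosomal protein genes and the annotated tRNA genes were also added after the ribosomal protein result was seen, and serve only the weighing of that result. Alignments and signal tracks were not used here.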

Results

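The data were chromatin immunoprecipitation sequencing (ChIP-seq) peaks of E(spl)mδ-HLH, written E(spl)mdelta-HLH in the gene annotation. The protein is a basic helix-loop-helix repressor of the Enhancer of split complex, whose genes are switched on by Notch signalling. It was expressed with a GFP fused to its C-terminus in a transgenic Drosophila melanogaster line, and chromatin came from whole embryos of mixed sex aged 2 to 12 h. The design held 1 group of 2 biological replicates, so the questions it allows are where the peaks lay, near which genes, over which sequences, and how far the replicates shared them. The authors' thresholded list held 2750 peaks. Each replicate's own list and the list called on both replicates pooled held 30000 peaks apiece. The lists hold no read counts, so the sequencing depth is unknown and intervals cover counting error only. Peaks and genes are not independent replicates, and the p-values measure these lists, not the spread between embryo collections.

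The peaks of E(spl)mδ-HLH lay most densely over the Enhancer of split complex itself. The complex held 34 thresholded peaks in 53.4 kb of chromosome arm 3R (25992621 to 26046008, dm6). Random windows of that length on the arm held a mean of 1.13 peaks (permutation p = 0.0006). These windows could overlap the locus itself, and the highest count among them was also 34. Outside the complex no window of this length on 3R held more than 12, so this p counts only windows that overlapped the locus. All 12 listed genes of the complex had a summit within 2 kb of a transcription start site (TSS). E(spl)mbeta-HLH, a sister repressor gene, carried the peak with the second highest signal of the whole list (3R 26005922 to 26006231, signal 1431), with its summit 82 bp upstream of the TSS. It ranked 2 in replicate 1 and 1 in replicate 2.

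The factor's own gene, E(spl)mdelta-HLH (FBgn0002734, 3R 25997621 to 25998633, plus strand), had 4 peaks within 2 kb of its TSS. The strongest of them (3R 25996768 to 25997109) had a signal of 1029 and rank 6, and ranked 9 in replicate 1 and 5 in replicate 2. Its summit lay 674 bp upstream of that TSS and 49 bp inside the neighbouring gene CG43116, which is read from the other strand. A further peak (3R 25997391 to 25997581, signal 679) had its summit 106 bp from the E(spl)mdelta-HLH TSS. E(spl)m7-HLH (signal 719, rank 24) and E(spl)malpha-BFM, a Bearded family gene (signal 679, rank 29), had summits 32 bp and 55 bp upstream of their TSSs. At the other end of the range, the only peak near E(spl)m4-BFM had a signal of 118 and rank 2704. Of the 34 summits of the locus, 16 were intergenic and 13 were within 500 bp of a TSS. Outside the complex, no window of this length held more than 12 thresholded summits on 3R or more than 22 on any other arm, the 22 being on 2R (13541516 to 13594903).

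**Figure D1:**
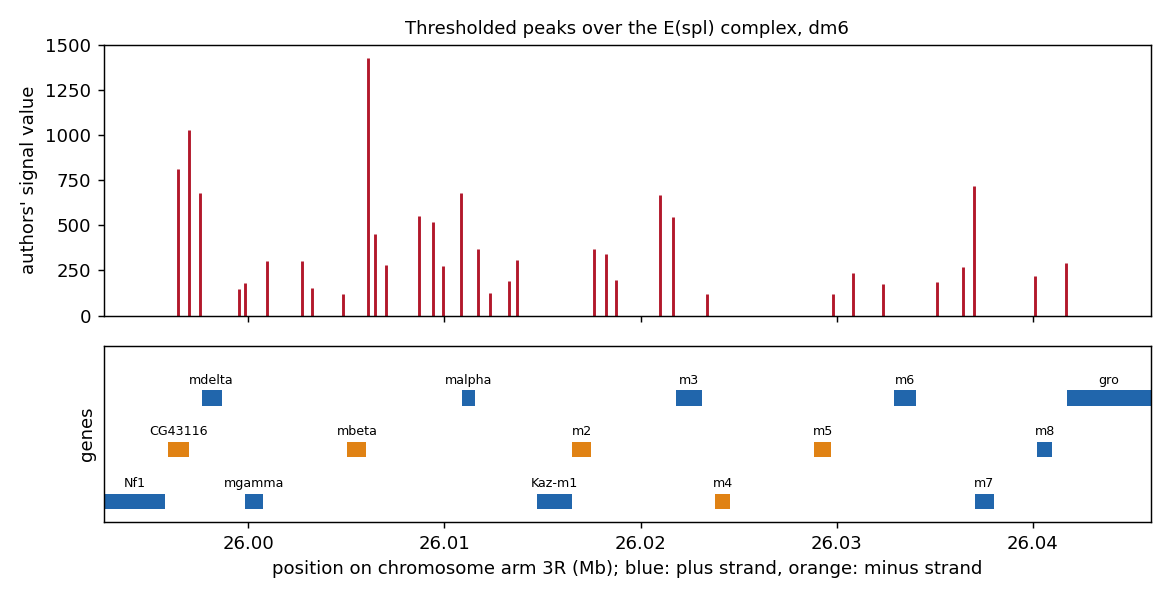
Thresholded peaks over the Enhancer of split complex, with the position on chromosome arm 3R (Mb, dm6) on the horizontal axis, the authors' signal value of each of the 34 peaks as a vertical line in the upper panel and protein-coding genes in the lower panel (names without the E(spl) prefix and family suffix). The highest line, signal 1431, stands at the TSS of E(spl)mbeta-HLH.

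The Bearded and achaete-scute complexes, gene clusters of the Notch pathway and of neural precursor formation, held few peaks. The Bearded complex on 3L (14940499 to 14981040) held 2 peaks against a random mean of 0.861 (permutation p = 0.224), and none of its 4 matched genes, Brd, Tom, Ocho and BobA, had a summit within 2 kb of a TSS. The achaete-scute complex on X (365031 to 468176), which holds the proneural genes, also held 2 peaks against a mean of 1.61 (permutation p = 0.392). Both lay nearest to ase, with ranks 1584 and 1835, and ac, sc, l(1)sc and ase had no summit within 2 kb. In the top 2750 peaks of replicate 2 alone, both loci held 0 peaks.

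Beyond the complex, ribosomal protein genes were bound more often than other genes. Of 92 cytosolic ribosomal protein genes 69 (75.0%, exact binomial 95% interval 64.9 to 83.4) had a summit within 2 kb of a TSS, against 16.5% of the other 13853 protein-coding genes (odds ratio 15.2, adjusted p = 1.7e-33). RpS27 (3R 25247388 to 25247612, signal 1304), RpS4 (3L 13041673 to 13041920, signal 1213), RpL13A (3R 5624338 to 5624544, signal 992) and RpS28b (X 9554483 to 9554708, signal 974) held ranks 3, 4, 7 and 8. Their summits lay between 3 and 28 bp from the TSS. Among all protein-coding genes, 2354 of 13945 (16.9%) were bound in this sense. List tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 17 lists.

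Notch pathway genes were bound more often than other genes, with 12 of 21 members (57.1%, odds ratio 6.59, Fisher's exact test, adjusted p = 0.000192). The strongest were dx (signal 388), a cytoplasmic Notch regulator, kuz (386), the protease that cleaves Notch and its ligands, numb (349), a Notch antagonist in asymmetric division, and gro (293), the corepressor that E(spl) proteins recruit. N itself (signal 206, rank 798) and the ligand gene Delta (signal 263, rank 414) were bound, while Ser, Su(H), H and fng were among the 9 without a summit. The dx summit, 738 bp upstream of dx, lay 5 bp from the TSS of the ribosomal protein gene RpL7A, and the kuz summit, 884 bp upstream of kuz, lay 73 bp from that of B4. The gro gene adjoins the Enhancer of split complex. With the peaks of that locus left out, an alternative chosen after seeing the data, 52.4% of the list was bound (exact test, adjusted p = 0.00111, range over 8 alternatives 1.6e-06 to 0.0109).

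Neuroblast genes passed the test as well, with 12 of 23 bound (52.2%, odds ratio 5.39, Fisher's exact test, adjusted p = 0.000476). The growth regulator gene brat (signal 340) had 5 peaks within 2 kb of a TSS, the strongest of them nearer to Polr1D (121 bp) than to brat (1296 bp), and SoxN (279) and the polarity genes mira (278) and insc (243) followed. Kr, pros, vnd, Dr, esg, wor, grh and pdm2 were the other bound members, and dpn, hb, cas and nub were not bound. Of the 8 trachea and midline genes 6 were bound (75.0%, odds ratio 14.8, adjusted p = 0.0016 by Fisher's exact test), led by the FGF gene bnl (signal 256), the guidance cue gene sli (229) and salm (198). In the top peaks of replicate 1 alone the share was 50% (exact test, adjusted p = 0.0622, lowest over 8 alternatives 2.1e-05). Cell cycle genes were bound in 6 of 11 cases (54.5%, Fisher's exact test, adjusted p = 0.0139), with stg (278), E2f1 (228), CycB3 (227) and trbl (179) the strongest. That call ended against random gene sets matched on TSS number and gene spacing (permutation test, adjusted p = 0.131, lowest over 8 alternatives 0.00196).

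**Figure D2:**
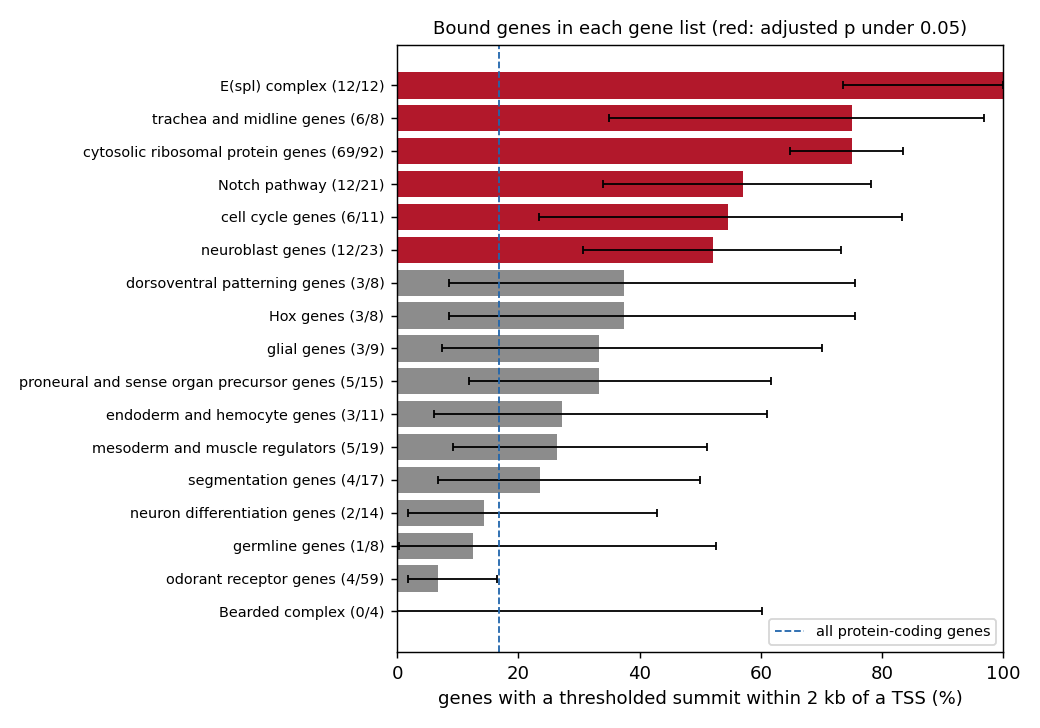
Share of genes in each list with a thresholded summit within 2 kb of a TSS (horizontal axis, %), with exact binomial 95% intervals as error bars, bound and matched genes in brackets, red bars for lists with an adjusted p under 0.05, and a dashed line at the 16.9% of all protein-coding genes. The E(spl) complex stands at 100% and the ribosomal protein genes at 75.0%.

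The other developmental lists did not pass the test, although single members carried strong peaks. Among proneural and sense organ precursor genes 5 of 15 were bound (exact test, adjusted p = 0.265), namely emc (signal 419, summit 23 bp upstream of the TSS), ato (385), hry (346), phyl (180) and nvy (129). The proneural activators sc, l(1)sc and amos and the sense organ gene sens were not. Segmentation genes had 4 of 17 members bound (23.5%, exact test, adjusted p = 0.622), bcd (232), odd (150), slp1 (125) and cad (118). Hox genes had 3 of 8 (37.5%, adjusted p = 0.262, exact test), lab (182), Abd-B (171) and Scr (118). The call for both lists depended on the replicate. In replicate 2 alone 41.2% of segmentation genes (exact test, adjusted p = 0.0346, highest over 8 alternatives 1) and 62.5% of Hox genes (exact test, adjusted p = 0.0124, highest 0.848) were bound, while in replicate 1 alone the shares were 11.8% and 25%. The Scr peak ranked 775 in replicate 2 and 11163 in replicate 1.

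Dorsoventral patterning genes were bound in 3 of 8 cases (adjusted p = 0.262, exact test), with brk (signal 172), tup (150) and dpp (147). Mesoderm and muscle regulators had 5 of 19 bound (exact test, adjusted p = 0.497), led by Mef2 (295), tin (202), stumps (168) and Doc3 (147). Glial genes had 3 of 9 bound (adjusted p = 0.283, exact test), moody (458), pnt (205) and repo (123). Endoderm and hemocyte genes had 3 of 11 bound (exact test, adjusted p = 0.537), the forkhead gene fkh (580, rank 42), ush (181) and srp (131). In the neuron differentiation list cpo (495, rank 70) and elav (248) were the 2 bound genes of 14 (exact test, adjusted p = 1), and in the germline list nanos (138) was the 1 of 8 (adjusted p = 1, exact test), with its summit nearer to CG11779 (72 bp) than to nanos (354 bp). That peak ranked 942 in replicate 2 and 4120 in replicate 1, and the germline share was 25% in replicate 2 alone and 0% in replicate 1 alone. Odorant receptor genes, which serve the sense of smell, were bound in 4 of 59 cases (6.78%, exact test, adjusted p = 0.0873), Or88a (217), Or9a (162), Or67d (154) and Or46a (125), with summits 761 to 1586 bp from their TSSs. The summits at Or88a, Or9a and Or46a were nearer to CG12402, Neb-cGP and CG18011. Within 500 bp of a TSS 0 of the 59 were bound (exact test, adjusted p = 0.00225, range over 8 alternatives 0.00184 to 0.625).

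The strongest 15 peaks fell on ribosomal protein promoters, the Enhancer of split complex and a few other sites. The highest signal (1477, 2L 14023954 to 14024232) was over an exon outside coding sequence and annotated UTRs, with hll the nearest protein-coding gene at 2941 bp. Next to the genes named above stood yps (signal 1054, rank 5), a cold shock domain RNA-binding protein gene, the chaperone gene Hsp83 (973, rank 9), RpL7 (968, rank 10) and RpL28 (801, rank 15), all with summits within 102 bp of the TSS. The remaining peaks were a coding exon 2814 bp upstream of CycY (922, rank 11), an intron of CG6333 (886, rank 12), an intron of the corepressor gene sbb 20091 bp from its TSS (843, rank 13) and a coding exon of CG43116 (813, rank 14). Each of the 15 ranked among the first 35 in replicate 1 and the first 17 in replicate 2.

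Promoters took most of the thresholded summits. Of 2750 summits 1524 (55.4%, exact binomial 95% interval 53.5 to 57.3) lay within 500 bp of a protein-coding TSS. After circular shifts of the summits along each chromosome arm the share was 11.5%, a ratio of 4.81. Coding exons away from promoters held 0.909% against 13.8%, 3' UTRs 0.80% against 4.42%, introns 25.8% against 39.8%, and intergenic sequence 13.1% against 28.1%. Other exons, outside coding sequence and annotated UTRs, held 2.80% against 1.62%, and 5' UTRs 1.2% against 0.774% (permutation p = 0.0594). Except for 5' UTRs, no shift came as far from the shifted mean on the observed side, and the permutation p of 0.0198 is the smallest that 100 shifts can give two-sided. The median summit was 300 bp from the nearest protein-coding TSS. In the top peaks of replicate 2 alone coding exons held 3.38% of summits.

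**Figure D3:**
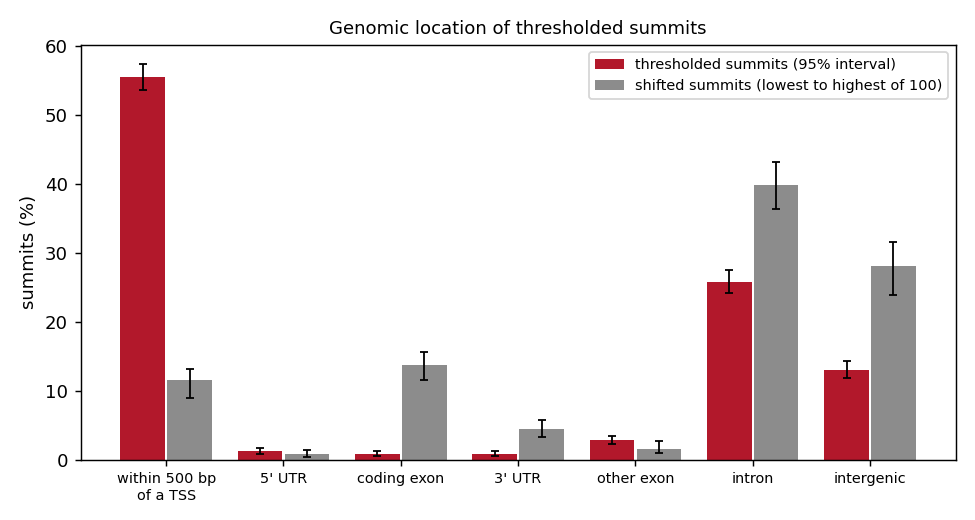
Share of summits (vertical axis, %) in each annotation class for the 2750 thresholded summits (red, exact binomial 95% intervals) and for 100 circular shifts of them (grey, mean with the lowest and highest shift). Summits within 500 bp of a protein-coding TSS made up 55.4% against 11.5% after shifting.

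Peak density differed between chromosome arms. Arm 2R held 24.9 summits per Mb (exact Poisson 95% interval 23.0 to 26.9), 2L 21.8 (19.97 to 23.8), 3L 20.6 (19.0 to 22.3) and 3R 20.6 (19.1 to 22.3). The X chromosome held 15.4 per Mb (13.8 to 17.05), below the interval of each of these 4 arms. Chromosome 4 held 5 summits, or 3.71 per Mb (1.204 to 8.66). These densities do not account for the number of genes per Mb or for the copy number of the X in embryos of mixed sex.

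Several short motifs were more frequent at summits, in windows of 50 bp on either side, than in the flanking sequence. GAGA repeats (GAGAGAG), bound by GAGA factor, occurred in 9.24% of summit windows (exact binomial 95% interval 8.18 to 10.4) against 2.65% of windows 500 bp to the left (exact McNemar test, adjusted p = 6.9e-25). The class C type E-box CACGCG occurred in 8.47% against 2.80% (exact test, adjusted p = 1.0e-19), and CACGTG, the class B E-box, in 3.35% against 1.53% (adjusted p = 4.4e-05). The N-box CACNAG was found in 17.1% against 12.5% (exact test, adjusted p = 4.2e-06) and the proneural E-box GCAGSTG in 5.82% against 3.60% (adjusted p = 0.000294). The extended E(spl) box occurred in 6 windows and in 0 control windows of 2750, which allows a control share of up to 0.109% (exact test, adjusted p = 0.0491), and in neither replicate alone did it pass. CATATG (3.64% against 3.82%), CACCTG, the Su(H) site (1.24% against 1.2%) and the Zelda-type site did not pass. The adjustment ran over 11 motifs.

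The E-box and N-box differences came with a difference in base composition. Summit windows had a mean GC content of 51.2% (SD 6.56) against 42.0% (SD 10.6) in the left windows. The sequence GTGCAC, which has the bases of CACGTG in another order and served as a control, was also more frequent at summits (4.0% against 2.73%, exact test, adjusted p = 0.0199). Against shuffles of the summit windows that keep dinucleotides, CACGCG differed by -0.0364 percentage points, CACGTG by -0.764 and the N-box by -3.49, whereas GAGA repeats stayed 6.65 percentage points above (exact test, adjusted p = 3.1e-31) and the proneural E-box 1.89 points (exact test, adjusted p = 0.00263), and CATATG turned to 1.45 points above and passed (exact test, adjusted p = 0.00263). Against windows matched on GC content and location class, an alternative chosen after seeing the data, the proneural E-box differed by -0.727 and the N-box by 1.13 points, and neither passed, while CACGCG stayed 4.84 points (adjusted p = 8.6e-14) and CACGTG 1.42 points (adjusted p = 0.00271, exact tests) above. The reordered control GTGCAC was 1.89 points above the matched windows (exact test, adjusted p = 0.00012), more than CACGTG. Against these windows CATATG was 1.45 points above (exact test, adjusted p = 0.00271). CACCTG turned to -2.65 points and passed as depleted (exact test, adjusted p = 0.00012). Motif shares hardly followed peak strength. Between the strongest 550 and the weakest 550 peaks, only the Zelda-type site differed, at 1.27% against 4.36% (Fisher's exact test, adjusted p = 0.0321), and CACGCG stood at 10.7% against 8.36% (adjusted p = 0.457). Between the strongest 1375 and the weakest 1375 peaks the Zelda-type call ended, at 2.62% against 3.85% (Fisher's exact test, adjusted p = 0.309).

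**Figure D4:**
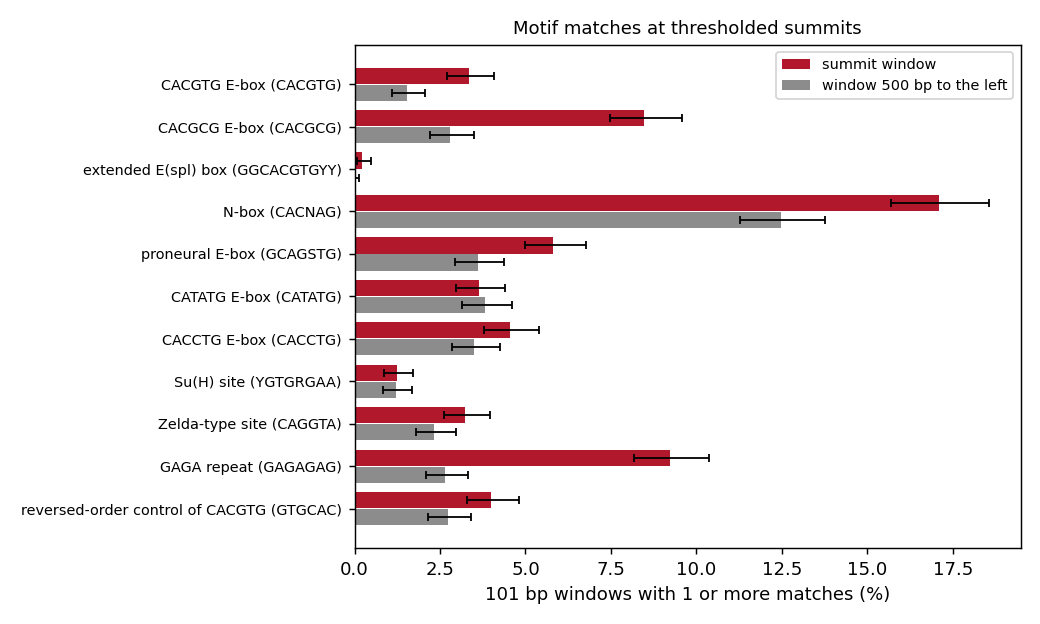
Share of windows of 50 bp on either side with at least 1 match (horizontal axis, %) for each motif at the 2750 thresholded summits (red) and in windows 500 bp to the left (grey), with exact binomial 95% intervals. GAGA repeats reached 9.24% against 2.65% and CACGCG 8.47% against 2.80%.

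The replicates shared most, though not all, of their strongest peaks. Of the top 2750 peaks of replicate 1, 1707 (62.1%, exact binomial 95% interval 60.2 to 63.9) overlapped a top 2750 peak of replicate 2, against 0.996% by circular shifts. The thresholded peaks had exactly the coordinates and signals of the first 2750 of the pooled list, and 2730 of them (99.3%) overlapped some peak in both full replicate lists, whose reads the pooled list shares. Of these thresholded peaks 83.5% were among the top 2750 of replicate 1, 76.5% among those of replicate 2 and 1.67% among neither. Among the weakest 2750 pooled peaks, 6.36% overlapped a peak in both replicate lists. Peaks at E(spl)mbeta-HLH, RpS27 and RpS4 stayed among the first 6 in either replicate, while those at slp1 (rank 877 in replicate 2, 4849 in replicate 1) and srp (1059 and 5560) did not keep their place.

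Signal ranks of matched peaks were moderately correlated between replicates. Over 2667 thresholded peaks with a summit within 100 bp in both lists, Spearman's rank correlation was 0.424, and over all 11100 matched peaks it was 0.598. These correlations run across peaks, which are not independent replicates, so no p-value was attached. A fit of the irreproducible discovery rate (IDR) to the matched peaks placed 3113 pairs at or under 0.05, of which 2482 (79.7%) overlapped a thresholded peak.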

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

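The tests of the flanks and summits of the Enhancer of split complex, of proteasome genes, of gene starts as a reference for tRNA genes and of matched and shuffled motif windows were chosen only after the results they bear on were seen. With 1 group in the design, no explanation that rests on a contrast between groups was tested.

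The thresholded list leaves out further pooled peaks that were also listed in both replicates. Of 3716 with a q value at or under 0.05, 3384 (91.1%) overlapped a peak in both replicate lists, which share their reads with the pooled list, so that overlap is no independent evidence of binding. The weakest 2750 pooled peaks had 28.7% of their summits in coding exons more than 500 bp from a protein-coding TSS. In the order of classes used above, where 5' UTRs come before coding exons, the share was 28.3% against 13.9% of the genome.

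For the dense peaks over the E(spl) complex, a candidate technical explanation is an extra genomic copy of this region carried by the transgene, which would raise background across a block. The 20 kb on either side of the locus held 20 pooled peaks outside the thresholded list against a random mean of 8.38 (permutation p = 0.0548), and the locus itself 32 against 11.3 (permutation p = 0.0147). Of the 34 thresholded peaks 22 had at least 2 times the lowest thresholded signal, but neither the number of copies nor how the signal scales with it is known, so an extra copy stays open. Of the 34 thresholded summits 38.2% lay within 500 bp of a TSS against 27.6% of the bases of the locus (exact binomial p = 0.18), which leaves focal binding at the promoters of the complex open as well. The extent of the transgene and the genotype of the control are not given in the sources used here.

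Peaks at ribosomal protein genes were weighed next. Genes picked by name as proteasome core genes were bound in 0 of 25 cases against 16.9% of other genes (Fisher's exact test, p = 0.015, and 0.0516 against matched gene sets). Whether all 25 are housekeeping genes was not checked. As far as they are, these values argue against a preference for housekeeping promoters of every kind. Translation factor genes were bound in 23 of 52 cases (44.2%, odds ratio 3.93, Fisher's exact test, p = 3.5e-06, and 0.0002 against matched gene sets, the smallest these can give), mitochondrial ribosomal protein genes in 10 of 73 (13.7%, p = 0.534), and the 3 groups together in 22% against 16.8% (p = 0.0998, and 0.0392 against matched gene sets), so highly expressed housekeeping genes as a class stay open. Of 290 tRNA genes 8.28% had a summit within 500 bp, 3.80 times the mean of 100 circular shifts, but starts of protein-coding genes reached 5.21 times theirs, so the shifts do not decide on a preference for highly transcribed loci. CACGTG or CACGCG was found in 11 of the 82 peaks near ribosomal protein genes (13.4%) against 11.03% of other peaks near a TSS (Fisher's exact test, p = 0.474). Most of the 82 thus lacked both E-boxes within 50 bp of the summit, which argues against these sites as the cause of most of these peaks. A part of E-boxes in the 11 stays open.

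The motifs at summits were weighed last. Against windows matched on GC content and location class, CACGTG or CACGCG occurred 6 percentage points more often at summits (11.5% against 5.45%, exact McNemar p = 4.0e-16) and GAGA repeats 7.6 points more often (p = 4.0e-37), which argues against GC content and location as the whole cause of either. The control sequence GTGCAC was also 1.89 points above its matched windows (exact test, adjusted p = 0.00012). That is more than the 1.42 points of CACGTG alone and less than the 4.84 points of CACGCG. Dinucleotide content stays open for the E-boxes, since shuffled summit windows held CACGTG or CACGCG as often as the summits (difference -0.764 points, exact McNemar p = 0.381).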

How the results depend on the processing

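Matched motif windows and lists without the E(spl) complex peaks were chosen after seeing the data, and all other alternatives before. Of 276 alternative values, 207 kept their direction and side of the threshold or stayed within the range counted as unchanged, 12 lost a call, 12 gained one, 25 changed direction and 20 moved beyond that range. The E(spl) complex, ribosomal protein, Notch pathway and neuroblast lists and the E(spl) complex locus passed under every alternative run on them, as did the GAGA repeats, except that the E(spl) complex list had 0 genes bound once its own peaks were left out (exact test, adjusted p = 0.367). The cause was not tested for the changes below, which unknown depth also limits. No paired analysis was possible because there was only 1 group.

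Replicate overlap was 55.5% at 50% reciprocal overlap and 59.6% for the top 500 peaks. The rank correlation was -0.0268 for thresholded peaks ranked by q, where most are tied at the ceiling, and for all matched peaks 0.585 by q and 0.629 with summits within 50 bp. At an IDR of 0.01, 1987 pairs remained under the threshold. With 1000 bp as TSS distance, 64.5% of summits were near a TSS, 21.0% in introns and 10.5% intergenic.

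By the gene with the nearest TSS, lists that then passed were proneural (46.7%), Hox (50%), dorsoventral (50%) and mesoderm (42.1%) genes, and odorant receptors passed as depleted (1.69%). They did so too within 500 bp (0%) and with gene body or 5 kb (10.2%). Cell cycle genes no longer passed with gene body or 5 kb (63.6%) or matched gene sets (permutation test, adjusted p = 0.131). Lists that passed neither before nor after but changed direction against other genes were Bearded (25%) and neuron differentiation genes (21.4%) by nearest TSS, Bearded (50%), germline (62.5%) and neuron differentiation genes (35.7%) with gene body or 5 kb, germline genes within 500 bp (12.5%), and segmentation (5.88%) and neuron differentiation genes (14.3%) in the strongest 1375 peaks.

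Against dinucleotide shuffles the difference in percentage points was -0.764 for CACGTG, -0.0364 for CACGCG, 0.145 for the extended E(spl) box, -3.49 for the N-box (now passing as depleted), 1.45 for CATATG (passing), -0.0364 for the Su(H) site and -0.691 for both CACCTG and GTGCAC. Against matched windows it was 0.182 for the extended E(spl) box, 1.13 for the N-box, -0.727 for the proneural E-box, 1.45 for CATATG (now passing) and -2.65 for CACCTG (passing as depleted). In the strongest 1375 peaks the extended E(spl) box (0.291), the proneural E-box (1.67) and GTGCAC (1.31) did not pass, and the Su(H) site turned to -0.0727. With right control windows CACCTG passed (1.24) and CATATG turned to 0.364. Between the strongest and weakest 1375 peaks the Zelda-type site differed by -1.24 and did not pass, and without passing the N-box turned to 0.727 and GTGCAC to -0.145. The Bearded and achaete-scute loci held 0 of the strongest 1375 peaks.

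With 1 replicate alone, summits near a TSS ranged from 52.4% to 54.9%, bound segmentation genes from 11.8% to 41.2%, Hox genes from 25% to 62.5%, germline genes from 0% to 25%, trachea and midline genes from 50% to 75% and odorant receptors from 3.39% to 8.47%. The extended E(spl) box ranged from 0.145 to 0.291 points, CACCTG from 0.40 to 1.27 and the Su(H) site from -0.109 to 0.218, and the Bearded and achaete-scute loci each held 0 to 2 peaks. Segmentation and Hox genes and CACCTG passed without replicate 1, and without replicate 2 odorant receptors passed as depleted and trachea and midline genes did not pass. Of 65 named peaks 10 fell outside the top 2750 of a replicate.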

Other observations

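All comparisons in this part were chosen after seeing the data. Summits inside the Enhancer of split complex held Su(H) sites, the binding sites of the Notch pathway's own transcription factor, more often than other summits. They were found in 4 of the 34 summit windows of the complex (11.8%) and in 30 of the 2716 others (1.10%, Fisher's exact test, adjusted p = 0.00765 over 11 motifs). The 34 windows come from 1 locus and are not independent. Sequence of the locus away from summits was not compared, so a locus rich in Su(H) sites cannot be told from sites at its peaks. The E-boxes CACGTG and CACGCG were each found in 1 of the 34 windows, and GAGA repeats in 0 of 34 against 9.35% of the others (exact test, adjusted p = 0.35). Among the 82 peaks near ribosomal protein genes, GAGA repeats were found in 1 (1.22%) against 9.64% of other peaks near a TSS (Fisher's exact test, p = 0.00549). Of the strongest 100 peaks 25 lay within 2 kb of the TSS of a ribosomal protein gene.

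Peaks among the top 2750 of 1 replicate that overlapped no top peak of the other differed in kind. Of 1044 such peaks in replicate 2, 7.76% had summits in coding exons more than 500 bp from a protein-coding TSS, against 1.25% of 1043 in replicate 1 (Fisher's exact test, p = 1.1e-13, which compares these libraries). Mean GC content was 53.5% and 49.5%. Peaks of replicate 2 alone were near 4 of 8 Hox genes, 6 of 17 segmentation genes and 6 of 23 neuroblast genes, and those of replicate 1 alone near 0, 1 and 1. Among lists that leaned the other way, replicate 1 alone had peaks near 6 of 21 Notch pathway and 16 of 92 ribosomal protein genes. Replicate 2 alone had them near 3 and 10 (exact McNemar test, adjusted p = 0.85 for each). The Hox, segmentation and neuroblast differences did not pass an exact McNemar test (adjusted p = 0.708 for each). For the Hox genes the test could not have passed. All 4 genes that differed were near peaks of replicate 2, and p = 0.125 (exact McNemar test) is the smallest that 4 genes can give.

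Genes on the X chromosome were bound in 338 of 2196 cases (15.4%) against 2016 of 11749 (17.2%) on the autosomes (odds ratio 0.878, Fisher's exact test, unadjusted p = 0.0437). The copy number of the X in embryos of mixed sex was not accounted for.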
